A study of Mus musculus with 12 samples.

How the data were processed

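Gene expression was measured in the cerebellum of 12 BALB/c mice on 12 Affymetrix arrays with biotin-labelled RNA, per the labels. The mice were Npc1+/+ (wild type) or Npc1-/- (null) and were killed at postnatal day 21 (P21) or 49 (P49). Each of the 4 groups held 3 arrays, and per the labels every replicate was an individual animal. Per the labels' protocols, genotype was determined by PCR, the tissue was kept in RNA stabilisation reagent, RNA was extracted with an organic reagent followed by a column kit with DNase treatment, and labelling followed Affymetrix. One protocol text gives P21 as the age at death for all animals, whereas the time point label of each animal and the series design give P21 and P49; the time point labels were used. Per the labels 11 animals were female and 1, P49 null replicate 1, was male.

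The authors deposited 1 intensity per probe set and array on a linear scale, for 22690 probe sets of which 64 are controls. The algorithm that summarised the probes and the scaling are not given in the sources used here. From the values, the mean after trimming 2% at each end was 5002 on every array, while the medians differed, and no centring or log transformation had been applied. The highest number of probe sets with identical values in a pair of arrays was 33 of 22690, so no array appeared to be deposited in duplicate. Detection calls and background estimates were not used here, so which dim genes lie above background is not known. The size of a change is uncertain where a group has a mean below the intensity at the filter. The genes named for which this holds in at least 1 group include Alas2, Aplnr, Apoc1, Cd14, Cd44, Cd68, Cdkn1c, Clec7a, Comp, Ebf2, Fcer1g, Fcgr3, Grik1, Lgals3, Lgals3bp, Lmo7, Mpeg1, Npc1, Olfml3, Slc5a1, Th and Zap70. Genes were named through the platform's probe annotation, updated by Entrez identifier with a RefSeq gene table of assembly GRCm38.p6 that was used for names alone. Of the probe sets, 20380 that are not controls had 1 gene symbol, 691 had several and 1555 were not listed with a gene. Matching by identifier was counted over the whole platform annotation without leaving out controls. There 20364 single-symbol probe sets were matched and 29 were not, so these do not add up to 20380. Positions on the genome are not given because the files name no build.

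The choices that follow were made before the data were examined, unless stated otherwise. Intensities were transformed as log2(value + 16). Array medians on that scale ranged from 10.65 to 10.92, a range of 0.27 that exceeded the limit of 0.15 set for using the values as deposited, while the 75th percentiles had a range of 0.09. The values were therefore quantile normalized. Fold changes are on this log2(value + 16) scale, which understates the change of dim genes. Each gene was represented by the probe set with the highest mean among those with 1 symbol, and genes were kept when that mean reached the 40th percentile of the non-control probe sets, an intensity of 959. Of 12393 genes, 7835 were tested and 4558 were below the filter.

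The 5 comparisons were null against wild type at P21, the same at P49, the difference between those differences (interaction), and P49 against P21 within each genotype. They were tested as contrasts of 4 group means in limma 3.58.1 with R 4.3.3, using eBayes with a mean-variance trend and all 12 arrays. All tests were two-sided, adjusted p-values are Benjamini-Hochberg values over the 7835 genes, and the threshold was 0.05. Errors of log2 differences are limma's standard errors with n = 3 animals per group unless called SD. Every adjusted p in the text comes from limma. The share of genes whose 3 and 3 values do not overlap by chance is 10%.

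Fixed lists of marker and pathway genes (29, with 728 members across all 30 lists including a sex-linked list used only to check labels) were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Of the members, 620 had a probe set and 474 were tested, and the 28 lists with at least 3 tested members entered the test. The filter took the mean over all 12 arrays. A member dim in the other groups could therefore be tested only because it is high in P49 null arrays, which favours rises in those arrays. Only Alas2 remained of the list of blood cells, so that list was not tested. Adjusted p-values for lists are over the 28 lists within a comparison. Several lists share members, so their tests are not independent.

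Genes were named by a rule. It takes Npc1, the 10 genes with the largest called rise and the 10 with the largest called fall whose groups do not overlap (5 each way for age in Npc1 null), and up to 4 members of each described list with the smallest p. Where fewer than 10 genes were called, the 5 with the smallest p in each direction are named. Names of the clone or numbered kind are counted and not named. Lyz1 and Lyz2 are close paralogs whose probe sets may share signal, so the level of each is uncertain. Among 69 pairs of a named gene and a comparison with a further probe set, 112 further probe sets were compared, 2 had the opposite sign and 0 of these passed limma's threshold in the opposite direction. Further probe sets here and below are those that reached the intensity filter, so dimmer ones were not compared. Genes named only as list members were compared only where called.

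The model was tested on simulated data in which 200 of 7835 genes were changed by log2 0.5, 1 or 2. For the genotype difference at P21 it recovered 31.3%, 77.6% and 98.5% of them with 6 false calls among 144, and at P49 44.8%, 77.6% and 97.0% with 7 false calls among 153. The simulated noise was independent between genes and had the same spread on every array, so no array stood apart. The 144 simulated calls also set a looser cut-off than the 5 calls of the real data at P21. These shares are therefore not the power of the real P21 comparison.

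Alternatives covered the values as deposited, an offset of 64, a floor of 32, no filter, a filter at the 60th percentile, every probe set, the average of a gene's probe sets, eBayes without a trend or with robust estimation, array weights, an adjusted p under 0.01, a change of at least 1.5-fold, the replicate number as a block, sex as a covariate, only the arrays of the 2 groups compared, and each array left out in turn. An offset of 512, leaving out 3 P21 arrays with doubtful sex labels, and the choroid plexus median as a covariate were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.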

Results

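The cerebellum of wild-type and Npc1-null BALB/c mice was profiled at postnatal days 21 and 49 with 3 animals in each of 4 groups. Npc1 encodes a late endosomal and lysosomal protein that moves cholesterol out of these compartments, and its loss is the cause of Niemann-Pick type C disease. The design asks how the cerebellum of null animals differs from that of wild-type animals at each age, whether this difference itself changes with age, and what changes with age in each genotype.

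Npc1 itself was lower in the null arrays at both ages. All 6 null arrays, from 8.25 to 10.53 on the log2 intensity scale, lay below all 6 wild-type arrays, from 11.06 to 11.75. The difference was -1.95 ± 0.37 at P21 (adjusted p = 0.101) and -1.43 ± 0.37 at P49 (adjusted p = 0.0591), so neither passed the threshold of limma. The test of Npc1 genotype at P21 passed without null P21 replicate 1 (adjusted p = 0.0113) or null P21 replicate 2 (0.0318), and over all alternatives its adjusted p at P21 ran from 0.0113 to 0.799. The test of Npc1 genotype at P49 passed without null P21 replicate 1 (0.0197) or null P21 replicate 2 (0.000816), with a range over alternatives of 0.000268 to 0.289. The labels do not say which allele this is or whether the probe set lies in the altered part of the transcript, so its level is only a partial check of the genotype.

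The sex-linked genes did not follow every label. Xist, which is transcribed from the inactive X chromosome of females, lay between 15.61 and 15.86 on 9 arrays, including P49 null replicate 1, the only array labelled male. It was 9.28 on wild-type P21 replicate 2, 13.01 on null P21 replicate 2 and 13.36 on null P21 replicate 3, which are labelled female. On the same arrays the Y-linked gene Eif2s3y was 12.72, 9.25 and 12.67. Eif2s3y was 7.93 on P49 null replicate 1. Every P49 array was thus at the female level of Xist, while these P21 arrays, 1 wild-type and 2 null, were not. Sex by these genes is therefore unbalanced between the ages in both genotypes, and between the genotypes at P21. Directions drawn from P21 therefore rest on arrays of which 3 carry a doubtful sex label, and results without these 3 arrays, chosen after seeing the data, stand beside the counts.

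**Figure D1:**
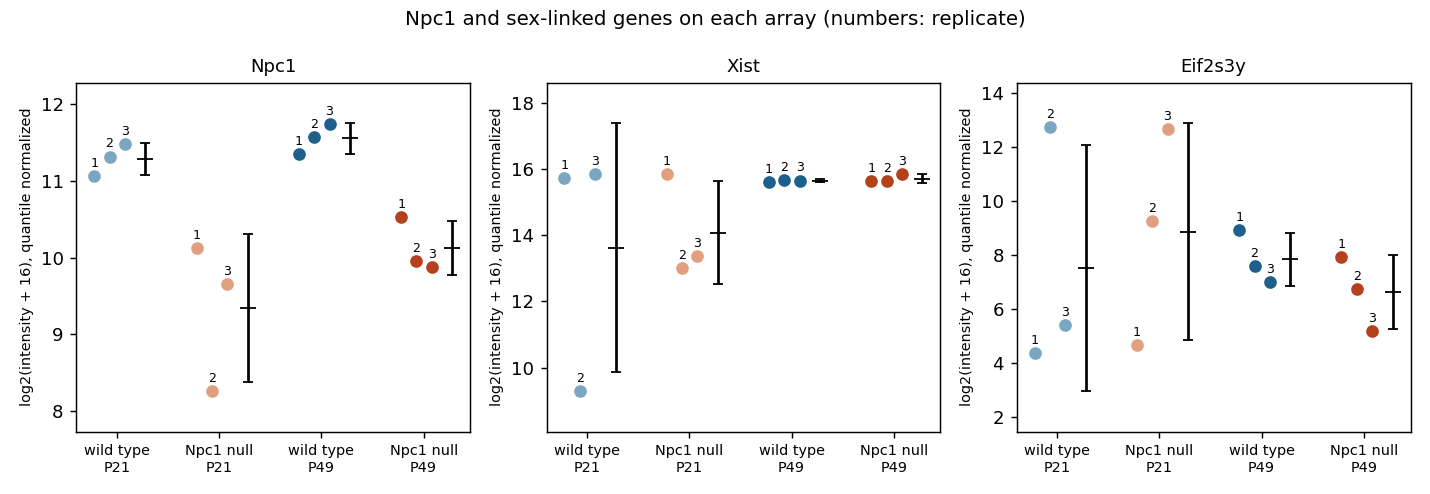
Log2 intensity (value + 16, quantile normalized) of Npc1, Xist and Eif2s3y on each array by group, with the replicate number above each point and the group's mean and SD as a bar (n = 3). All Npc1 null arrays lie at or below 10.53 and all wild-type arrays at or above 11.06, while Xist is 9.28, 13.01 and 13.36 on 3 P21 arrays labelled female.

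At P21, markers of microglia and the macrophage lineage were higher in null cerebellum and the myelin list was lower. Mpeg1, which encodes a pore-forming protein of macrophages, rose by log2 4.15 ± 0.36 (adjusted p = 0.000151). Its wild-type P21 values of 6.56, 7.66 and 8.15 are not shown to be above background, since Eif2s3y reached 8.91 on an array with Xist at the female level, so the size of this rise is uncertain. The complement subunit genes C1qb and C1qc, which microglia express, rose by log2 1.27 ± 0.16 and 2.63-fold with a log2 error of 0.18 (adjusted p = 0.00492 for both). The 2 further probe sets of C1qb gave 1.00 (adjusted p = 0.107) and 0.89 (0.445) and did not pass. B2m, the light chain of MHC class I, rose by 0.93 ± 0.13 (adjusted p = 0.0128), and its further probe set gave 1.22 (0.00103). Zap70, a T cell receptor kinase, was the only gene called lower, at -2.54 ± 0.40 (adjusted p = 0.0298). C1qa at 1.08 ± 0.18 (0.0524) and the myelin genes Cldn11 at -0.86 ± 0.15 (0.0524), Mal at -1.08 ± 0.21 (0.109) and Gsn at -0.55 ± 0.11 (0.109) had the next smallest p-values and did not pass. A further probe set of Mal gave -1.34, and of 4 further probe sets of Gsn 3 gave -0.78, -0.66 and -0.64 and 1 gave 0.08.

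Of the 17 microglia core genes tested at P21, 2 rose, 7 when adjusted over the list alone, and 15 had positive differences. The list shifted up with a median of 0.34 (camera adjusted p = 1.7e-09; adjusted p = 0.0372 with an estimated correlation). None of the 15 genes of activated, phagocytic microglia was called in limma over all genes, although 9 were when adjusted over the list alone, and the list shifted up with a median of 0.43 (adjusted p = 4.66e-08; adjusted p = 0.0449 with an estimated correlation). Its members Clec7a (1.04 ± 0.22, adjusted p = 0.154), Cd68 (1.47 ± 0.36, 0.263) and Lgals3 (1.27 ± 0.35, 0.328) did not pass. All 30 myelin and mature oligodendrocyte genes had negative differences, none passed over all genes, and 13 passed when adjusted over the list alone. The myelin list shifted down with a median of -0.42 (adjusted p = 2.27e-16; adjusted p = 0.0372 with an estimated correlation). The list of brainstem neurons, a neighbouring tissue, had the same median of -0.42 with all 5 genes negative and none called in limma or adjusted over the list alone (adjusted p = 0.0213; adjusted p = 0.435 with an estimated correlation). Wild-type P21 replicate 3 had the highest P21 median of both lists, 0.17 for myelin and 0.39 for brainstem neurons. The shift brainstem_neurons genotype at P21 list was lost without wild-type P21 replicate 3 (0.49) or null P21 replicates 1 and 3 (0.24, 0.0972). The interferon response list of 6 genes had a median of 0.64, with Ifitm3 at 1.04 ± 0.19 (adjusted p = 0.0971), and its call was lost (adjusted p = 0.0522 with an estimated correlation). Complement (median 0.67; adjusted p = 0.0679 with an estimated correlation), antigen presentation (0.34; adjusted p = 0.0549 with an estimated correlation) and lysosome (0.08; adjusted p = 0.178 with an estimated correlation) lost theirs as well. The cholesterol synthesis list had a median of -0.13 with 0 of 19 genes called by limma and 2 lower when adjusted over the list alone (adjusted p = 0.157 with an estimated correlation). The 30 Purkinje cell genes had a median of 0.00, with 15 above and 15 below 0 and no call (adjusted p = 0.99).

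In limma, 4 genes were higher and 1 was lower at P21 of 7835 tested, all 5 with groups that do not overlap, beside 790 genes at an unadjusted p under 0.05. Over all genes, 11.8% had groups that do not overlap, against 10% by chance. On the values as deposited 5 were higher and 3 lower. With only the arrays of the 2 groups 1 of the 5 calls was shared. Without null P21 replicate 1 there were 14 higher and 13 lower. The count of lower genes was 3 without null P21 replicate 2, and 0 without wild-type P21 replicate 1, 2 or 3, wild-type P49 replicate 1 or null P49 replicate 1 or 2. Without the 3 doubtful arrays 2 were higher and 3 lower, and 2 of the 5 calls were shared, but this leaves 1 null array at P21, which is assumed to vary like the other groups. B2m genotype at P21 lost its call without wild-type P21 replicate 1 (adjusted p = 0.101), wild-type P21 replicate 2 (0.124) or null P21 replicate 3 (0.065). Zap70 genotype at P21 lost its call without wild-type P21 replicate 1 (0.172), 2 (0.125) or 3 (0.154), null P21 replicate 2 (0.0565), wild-type P49 replicate 1 (0.0651), or null P49 replicate 1 (0.0509) or 2 (0.0724). C1qb genotype at P21 and C1qc genotype at P21 lost their calls with only the arrays of the 2 groups (0.163 for both) and without the 3 doubtful arrays (0.0997 and 0.107), and C1qb also with the average of probe sets (0.0928). Over all alternatives the adjusted p ran from 0.00191 to 0.163 for C1qb, 0.00285 to 0.163 for C1qc, 0.000793 to 0.276 for B2m and 0.00128 to 0.224 for Zap70.

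At P49 the null cerebellum differed from wild type much more widely. Genes of microglia and phagocytes had the largest rises, the astrocyte filament gene Gfap rose, and Purkinje cell genes fell. Mpeg1 rose by log2 5.65 ± 0.36, the lysozyme genes Lyz1 and Lyz2 by 5.03 ± 0.48 and 4.46 ± 0.36, the galectin gene Lgals3 by 4.07 ± 0.35 and the phagocyte lysosomal membrane gene Cd68 by 3.76 ± 0.36. The pattern receptor Clec7a rose by 3.61 ± 0.22 and the signalling adaptor Tyrobp by 3.55 ± 0.17 (adjusted p = 5.82e-08). C1qc rose by 3.52 ± 0.18 and C1qa by 3.39 ± 0.18. Gfap, the intermediate filament of astrocytes, rose by 3.30 ± 0.17 (9.85-fold, adjusted p = 5.82e-08). The sizes are uncertain for Mpeg1, whose wild-type P49 values of 8.77, 7.88 and 7.65 are not shown to be above background, and for Lgals3, Clec7a, Cd68, Th, Cd14, Cd44, Apoc1 and Lgals3bp, whose wild-type P49 means of 8.67, 8.85, 9.53, 9.51, 9.61, 9.62, 9.62 and 9.90 lie below the intensity of the filter (959). The same holds for the falls of Ebf2, Grik1, Lmo7 and Slc5a1, with null P49 means of 9.60, 9.45, 9.65 and 9.87. Of the 12 fits without 1 array, Mpeg1 passed the filter in 10 and Clec7a in 9. Clec7a did not pass when a P49 null array was left out, so these arrays helped decide that it was tested.

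The 10 largest called falls included 2 genes of the Purkinje cell list, Itpka and Icmt. Itpka, an inositol trisphosphate kinase, fell by 1.60 ± 0.23 (adjusted p = 0.00122), Icmt, a carboxyl methyltransferase, by 1.46 ± 0.17 (0.000258). Smaller falls in that list were those of the transcription factor gene Ebf2, by 1.16 ± 0.19 (0.00372), and of Rgs8, a regulator of G protein signalling, by 1.09 ± 0.15 (0.000587). The glycosyltransferase gene B3gnt5 fell by 1.60 ± 0.19 (0.000254) and Smpx by 1.45 ± 0.21 (0.00114). Nrk was -1.68 ± 0.38 (adjusted p = 0.0309), with further probe sets at -1.69 (0.145) and -1.42 (0.04), Fgf7 -1.55 ± 0.31 (0.013), Lmo7 -1.35 ± 0.28 (0.0175), the calcium release channel Ryr1 -1.33 ± 0.26 (0.0108), the glutamate receptor subunit Grik1 -1.29 ± 0.29 (0.0278) and the glucose cotransporter Slc5a1 -1.29 ± 0.27 (0.0184). The tests Nrk genotype at P49, Fgf7 genotype at P49, Lmo7 genotype at P49, Ryr1 genotype at P49, Grik1 genotype at P49 and Slc5a1 genotype at P49 lost their calls when certain single arrays were left out. Without null P49 replicate 2 the adjusted p was 0.18 for Nrk, 0.0864 for Fgf7, 0.111 for Lmo7, 0.0775 for Ryr1, 0.14 for Grik1 and 0.106 for Slc5a1. Without null P49 replicate 3 it was 0.14, 0.0906, 0.115, 0.0683, 0.166 and 0.111 for Nrk, Fgf7, Lmo7, Ryr1, Grik1 and Slc5a1. Without wild-type P49 replicate 1 it was 0.129 for Nrk, 0.0651 for Fgf7, 0.0862 for Lmo7, 0.0507 for Grik1 and 0.0862 for Slc5a1. Without wild-type P49 replicate 2 it was 0.0939 for Nrk, 0.077 for Fgf7, 0.053 for Ryr1, 0.108 for Grik1 and 0.0671 for Slc5a1. Without wild-type P49 replicate 3 it was 0.0973 for Nrk, 0.0945 for Lmo7, 0.0596 for Ryr1, 0.123 for Grik1 and 0.0615 for Slc5a1. Over all alternatives it ran from 0.00115 to 0.18 for Nrk, 0.000252 to 0.0906 for Fgf7, 0.000703 to 0.115 for Lmo7, 7.53e-05 to 0.0975 for Ryr1, 0.00184 to 0.166 for Grik1 and 0.000554 to 0.111 for Slc5a1.

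Of the 17 microglia core genes 14 rose at P49 (15 adjusted over the list alone), with a median of 1.81 (adjusted p = 0.000245 with an estimated correlation). Of the 15 activated microglia genes 14 rose (15 adjusted over the list alone), with a median of 1.82 (adjusted p = 0.000245 with an estimated correlation). Of genes with a probe set, 15 of 29 were tested for this list, 17 of 27 for microglia core, 6 of 13 for complement and 6 of 24 for interferon response. For reactive astrocytes 12 of 24 were tested, and for antigen presentation 7 of 15. P49 null arrays helped decide which members passed the filter, so shares and medians of these lists may lean toward rises. The same holds for these lists in the interaction and with age in null animals. Of 41 lysosomal genes 17 rose and none fell, or 26 when adjusted over the list alone, with a median of 0.40 (adjusted p = 0.000678 with an estimated correlation). The proteases Ctsd, Ctss and Ctsz rose by 2.05 ± 0.12, 2.19 ± 0.18 and 1.82 ± 0.14, and Grn, which encodes the lysosomal protein progranulin, by 1.66 ± 0.13. Of 6 complement genes 3 rose (5 adjusted over the list alone; adjusted p = 0.00451 with an estimated correlation), and these 3 were the C1q genes, with C1qb at 3.06 ± 0.16 and its 2 further probe sets at 1.58 and 2.81. In the interferon list Lgals3bp (2.45 ± 0.36) and Ifitm3 (1.12 ± 0.19) rose, 2 of 6 genes and 3 when adjusted over the list alone. In the antigen presentation list B2m (1.70 ± 0.13) and Ctss rose, 2 of 7 genes and 3 when adjusted over the list alone. Both lists passed (adjusted p = 0.00682 with an estimated correlation). The median was 0.69 for interferon response and 0.22 for antigen presentation, whose mean was 0.68. Lgals3bp is also a member of the activated microglia list, and Ctss of the microglia core and lysosome lists. Neither list was tested without shared members, so a shift apart from the microglial rise is not shown.

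Of 12 reactive astrocyte genes 4 rose at P49 and all 12 had positive differences (9 adjusted over the list alone; adjusted p = 0.00682 with an estimated correlation). Besides Gfap these were the filament gene Vim (1.05 ± 0.17), the adhesion receptor Cd44 (1.63 ± 0.26) and Cd14 (1.82 ± 0.30), a receptor that microglia also express. The 2 further probe sets of Vim gave 0.74 (adjusted p = 0.0945) and 0.90 (0.0176). Only 12 of 24 reactive astrocyte genes with a probe set passed the filter, so the share of rises in that list may lean upward. In the list of astrocytes and Bergmann glia only the water channel Aqp4 rose, by 0.94 ± 0.13, 1 of 20 genes and 3 when adjusted over the list alone, and the list did not pass (adjusted p = 0.105). Of 30 Purkinje cell genes 20 fell and none rose, or 24 when adjusted over the list alone. The Purkinje list had a median of -0.81 and passed (adjusted p = 0.00917 with an estimated correlation). Granule neuron genes, 0 of 17 called in limma, had a median of 0.02 (adjusted p = 0.93), and genes of cerebellar interneurons, 0 of 11 called, had a median of -0.06 (adjusted p = 0.321). Of 13 cholesterol efflux genes 3 rose, namely the apolipoprotein genes Apoe (0.85 ± 0.13) and Apoc1 (0.99 ± 0.19) and the transporter Abca1 (0.75 ± 0.16), with 5 higher and 1 lower when adjusted over the list alone. The shift of that list was lost (adjusted p = 0.311 with an estimated correlation). No cholesterol synthesis gene of 19 was called in limma or adjusted over the list alone, and the list's median was -0.09 (adjusted p = 0.191 with an estimated correlation). The myelin list had a median of -0.12 with 1 of 30 genes, the protease gene Adamts4, lower at -0.66 ± 0.15, also 1 when adjusted over the list alone (adjusted p = 0.311 with an estimated correlation). Adamts4 genotype at P49 lost its call without wild-type P49 replicates 1, 2 and 3 (0.114, 0.102, 0.0846) or null P49 replicates 2 and 3 (0.171, 0.182), with an adjusted p of 0.00131 to 0.244 over all alternatives. Abca1 genotype at P49 lost its call without wild-type P49 replicates 1 and 2 (0.0771, 0.0862) or null P49 replicates 2 and 3 (0.12, 0.106), with an adjusted p of 0.000622 to 0.12 over all alternatives. Apoc1 genotype at P49 lost its call without null P49 replicate 3 (0.0657), with an adjusted p of 0.00119 to 0.0965 over all alternatives.

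The lists of choroid plexus and meninges had positive medians at P49 and lost their calls. The 3 choroid plexus genes tested had a median of 1.91, 0 were called in limma, and the list's call was lost (adjusted p = 0.311 with an estimated correlation). The meninges list had a median of 0.44 with 1 of 13 genes higher, the matrix gene Fmod at 2.65-fold with a log2 error of 0.30 (adjusted p = 0.374 with an estimated correlation for the list). The 3 further probe sets of Fmod gave smaller log2 rises of 1.08 (adjusted p = 0.182), 0.64 (0.246) and 0.87 (0.215) and did not pass. Fmod genotype at P49 lost its call without wild-type P49 replicates 1 and 2 (0.0862, 0.0898) or null P49 replicates 2 and 3 (0.104, 0.131), and its adjusted p ran from 0.000207 to 0.151 over all alternatives.

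**Figure D2:**
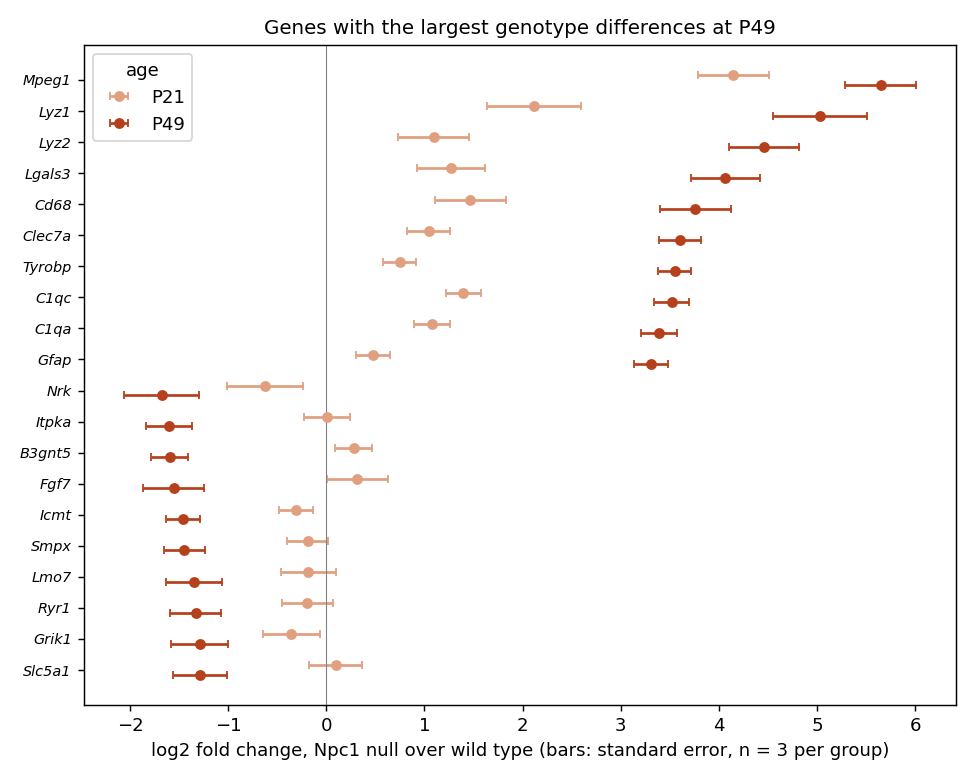
Log2 fold change of null over wild type (x axis) for the 10 genes with the largest called rise and the 10 with the largest called fall at P49 (y axis), at P21 and at P49, with limma's standard error as bars (n = 3 per group). Mpeg1, which is not shown to be above background in wild type, is 4.15 at P21 and 5.65 at P49, and Itpka is 0.00 at P21 and -1.60 at P49.

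In limma, 119 genes were higher and 89 lower at P49, and the groups of all 208 do not overlap, beside 887 genes at an unadjusted p under 0.05. Over all genes 23.2% had groups that do not overlap, against 10% by chance. The count of genotype at P49 genes higher was 190 without null P21 replicate 2, 71 without null P49 replicate 2 and 65 without null P49 replicate 3. The count of genotype at P49 genes lower was 42, 43 and 54 without wild-type P49 replicate 1, 2 and 3, 38 without null P49 replicate 2 and 35 without null P49 replicate 3. Without the 3 doubtful P21 arrays 209 were higher and 147 lower, and all 208 calls were shared. With the choroid plexus median as a covariate 140 of the 208 calls were shared.

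The interaction asked whether the genotype difference was larger at P49 than at P21. It was larger for genes of microglia and for Gfap, and it was more negative for Purkinje cell genes. Gfap differed by 2.83 ± 0.25 and Tyrobp by 2.80 ± 0.24 (adjusted p = 7.79e-05 for both), Clec7a by 2.56 ± 0.31 (0.00123), C1qa by 2.31 ± 0.26 (0.000929) and C1qc by 2.12 ± 0.25 (0.00123). Th, the rate-limiting enzyme of catecholamine synthesis, differed by 3.30 ± 0.53 (0.0111), with a genotype difference of -0.42 ± 0.38 at P21 (0.681) and 2.88 ± 0.38 at P49 (0.000541). B3gnt5 was the most negative at -1.87 ± 0.27 (0.00539), and Inpp4a, a phosphoinositide phosphatase, was -1.30 ± 0.20 (0.00717). B3gnt5 genotype by age interaction lost its call with the average of probe sets (0.154), in a range of 0.00101 to 0.154 over all alternatives, and a further probe set of Inpp4a gave -1.16 (0.336). For Mpeg1 the genotype difference was not shown to change with age (adjusted p = 0.39).

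Of the 17 microglia core genes 10 had a larger difference at P49 (14 adjusted over the list alone; adjusted p = 0.00117 with an estimated correlation), and of the 15 activated microglia genes 8 did (14 adjusted over the list alone; adjusted p = 0.00117 with an estimated correlation). Of 41 lysosomal genes 7 did, with Ctsd at 1.63 ± 0.17 and Ctss at 1.85 ± 0.26 (14 adjusted over the list alone; adjusted p = 0.00431 with an estimated correlation). Complement had 3 of 6 genes, also 3 adjusted over the list alone (adjusted p = 0.0137 with an estimated correlation), and reactive astrocytes 1 of 12, which was Gfap, and 4 adjusted over the list alone (adjusted p = 0.0468 with an estimated correlation). Of 30 Purkinje cell genes 4 were more negative at P49, namely Itpka, Ebf2, Cacna1g and Rgs8, and 23 when adjusted over the list alone, with a median of -0.73 (adjusted p = 0.0255 with an estimated correlation). Each of these 4 lost its call without certain arrays, and over all alternatives the adjusted p reached 0.183 for Itpka, 0.168 for Ebf2, 0.0742 for Cacna1g and 0.0976 for Rgs8. The myelin list had a positive median of 0.25 with 0 of 30 genes called in limma, and its call was lost (adjusted p = 0.201 with an estimated correlation).

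In limma 27 genes had a higher and 16 a lower interaction, beside 661 at an unadjusted p under 0.05. The count of higher genes was 17 without wild-type P21 replicate 3, 42 without null P21 replicate 2, 17 and 16 without wild-type P49 replicates 1 and 2, and 14 without null P49 replicate 2 or 3. The count of lower genes was 4, 10 and 5 without wild-type P21 replicates 1, 2 and 3, 3, 4 and 4 without wild-type P49 replicates 1, 2 and 3, and 29, 4 and 4 without null P49 replicates 1, 2 and 3. Without the 3 doubtful P21 arrays 28 of the 43 calls were shared. The number of lists that shifted was 7, and 14 without null P21 replicate 2.

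**Figure D3:**
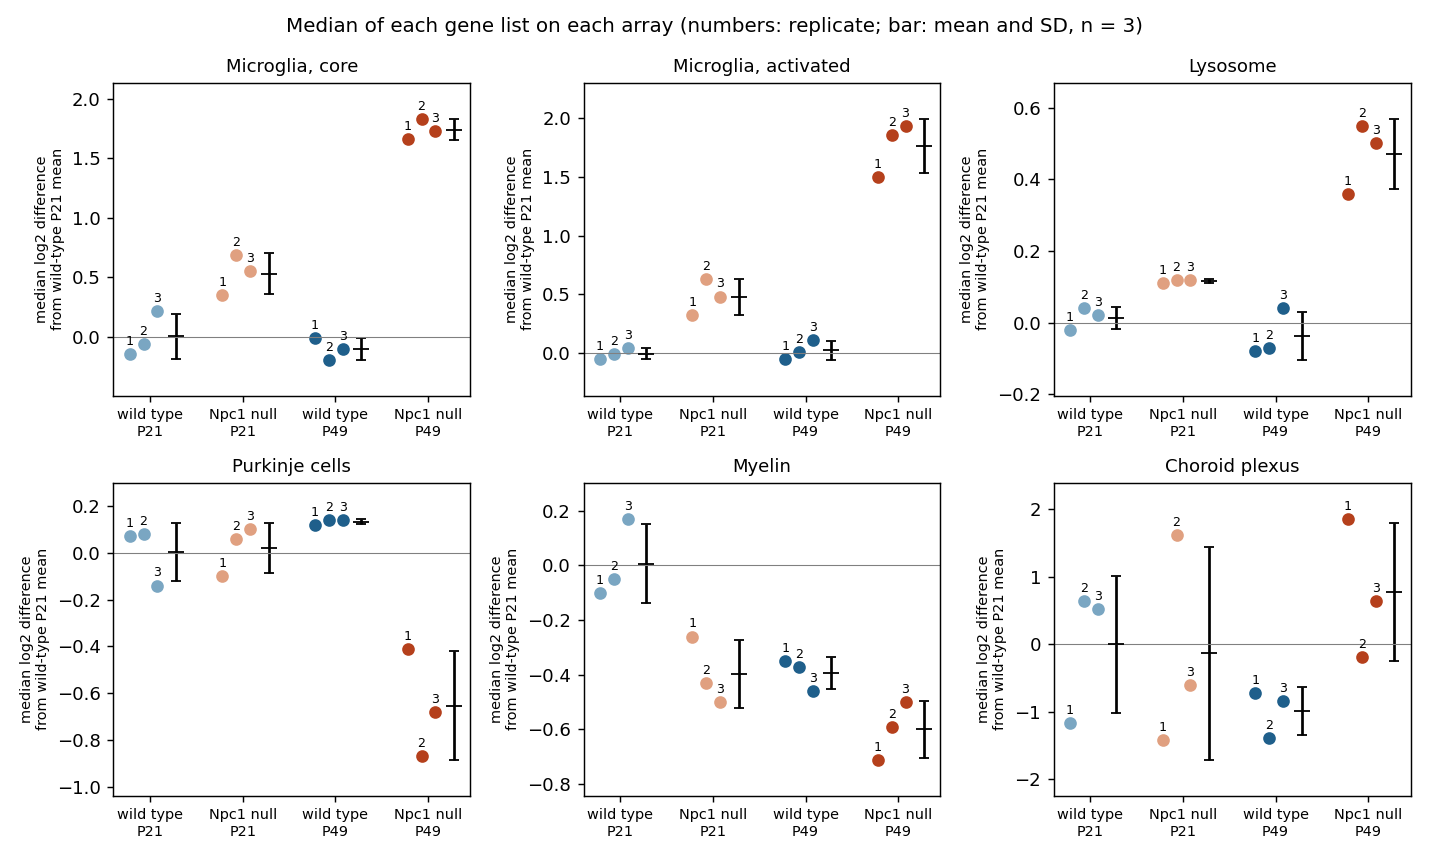
Median over each list's tested genes of the log2 difference from the wild-type P21 mean, on each array by group, with the replicate number above each point and the mean and SD of the 3 arrays as a bar; the y axes differ in range. The microglia core median of P49 null replicate 1 is 1.66 and those of the P21 null arrays run from 0.35 to 0.69, while choroid plexus medians spread widely within groups.

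In wild type, cholesterol synthesis genes were lower at P49 than at P21, and 8 myelin genes fell. Hmgcs1, which makes the HMG-CoA used for cholesterol, fell by 0.96 ± 0.12 (adjusted p = 0.00241), Sqle, the squalene epoxidase, by 0.92 ± 0.16 (0.0186), and Fdps, the farnesyl diphosphate synthase, was -0.69 ± 0.12 (0.0205). Of the 19 genes of that list 4 fell, 6 when adjusted over the list alone, 18 had negative differences, and the median was -0.37 (adjusted p = 0.0131 with an estimated correlation). The myelin genes Gsn (-1.37 ± 0.11, adjusted p = 3.77e-05), Ugt8a (-1.43 ± 0.20), which makes the myelin lipid galactosylceramide, Mog (-1.31 ± 0.20) and Cldn11 (-1.15 ± 0.15) fell. Of 30 myelin genes 8 fell, with 13 lower and 2 higher when adjusted over the list alone, and the list's median was -0.46, a call that was lost (adjusted p = 0.0719 with an estimated correlation). Among the largest falls were the collagen genes Col9a1 (-1.70 ± 0.22) and Col4a1 (-1.31 ± 0.21), the apelin receptor Aplnr (-1.65 ± 0.26), the syntaxin gene Stx1a (-1.62 ± 0.20), Cdkn1c (-1.54 ± 0.31), Necab3 (-1.43 ± 0.16) and Ppp1r1a (-1.35 ± 0.17). The largest rises were smaller, with Serpinb1a at 1.34 ± 0.24, Comp at 1.28 ± 0.26, Patj at 0.88 ± 0.15, Gstm1 at 0.78 ± 0.16, Gpld1 at 0.77 ± 0.15, Crebrf at 0.76 ± 0.12, Ntsr2 at 0.74 ± 0.14, Inpp4a at 0.70 ± 0.14, Rit2 at 0.68 ± 0.13 and Crtam at 0.53 ± 0.10. A further probe set of Inpp4a gave 0.04 (adjusted p = 0.985), those of Gstm1 0.24 (0.878), 0.70 (0.18) and 0.66 (0.2), of Rit2 0.65 (0.104), of Col4a1 -0.91 (0.377) and of Col9a1 -1.07 (0.0393), and of 4 further probe sets of Gsn 3 gave -1.60, -1.55 and -1.79 and 1 gave -0.25. Microglia core genes, 0 of 17 called in limma, had a median of -0.10 (adjusted p = 0.346).

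In limma 13 genes were higher and 42 lower with age in wild type, all 55 with groups that do not overlap (21.4% of all genes, against 10% by chance), beside 783 at an unadjusted p under 0.05, and 1 of them has a clone name. Of the 20 named genes Col9a1, Stx1a, Ugt8a, Necab3, Gsn and Ppp1r1a were called whichever array was left out. The count of higher genes was 2, 3 and 3 without wild-type P21 replicates 1, 2 and 3, 6, 1 and 1 without wild-type P49 replicates 1, 2 and 3, 20 and 43 without null P21 replicates 1 and 2, and 8 without null P49 replicate 2. The count of lower genes was 15, 12 and 16 without wild-type P21 replicates 1, 2 and 3, 13 and 15 without wild-type P49 replicates 2 and 3, and 69 without null P21 replicate 2. Without the 3 doubtful P21 arrays 53 of the 55 calls were shared.

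Calls with age in wild type often rested on single arrays, given here with limma's adjusted p without each and its range over all alternatives. Serpinb1a age in wild type lost its call without wild-type P21 replicates 1 and 3 (0.0574, 0.0522) or wild-type P49 replicates 1, 2 and 3 (0.066, 0.124, 0.0932), range 0.0047 to 0.124. Comp age in wild type did not pass without wild-type P21 replicates 1, 2 and 3 (0.0731, 0.149, 0.108), wild-type P49 replicates 2 and 3 (0.149, 0.202) or null P49 replicates 1, 2 and 3 (0.0619, 0.0612, 0.0647), range 0.00502 to 0.202. Patj age in wild type lost its call without wild-type P21 replicates 1 and 3 (0.0896, 0.0536) or wild-type P49 replicates 2 and 3 (0.115, 0.0997), range 0.00166 to 0.115. Gstm1 age in wild type did not pass without wild-type P21 replicates 1, 2 and 3 (0.114, 0.142, 0.222), null P21 replicate 3 (0.0609), wild-type P49 replicates 1, 2 and 3 (0.134, 0.187, 0.182) or null P49 replicates 1, 2 and 3 (0.0747, 0.0835, 0.0826), range 0.000261 to 0.222. Gpld1 age in wild type lost its call without wild-type P21 replicates 1, 2 and 3 (0.156, 0.0826, 0.118), wild-type P49 replicates 1, 2 and 3 (0.0554, 0.157, 0.179) or null P49 replicate 2 (0.0554), range 0.00431 to 0.179. Crebrf age in wild type did not pass without wild-type P21 replicate 2 (0.0574) or wild-type P49 replicate 3 (0.0609), range 0.000167 to 0.0609. Ntsr2 age in wild type lost its call without wild-type P21 replicates 1 and 2 (0.114, 0.126) or wild-type P49 replicates 1, 2 and 3 (0.0623, 0.124, 0.141), range 0.00129 to 0.141. Inpp4a age in wild type did not pass without wild-type P21 replicates 1, 2 and 3 (0.156, 0.0577, 0.172), wild-type P49 replicates 1, 2 and 3 (0.066, 0.176, 0.162) or null P49 replicate 2 (0.0593), range 0.00525 to 0.397. Rit2 age in wild type lost its call without wild-type P21 replicates 1, 2 and 3 (0.151, 0.0826, 0.149), wild-type P49 replicates 1, 2 and 3 (0.0623, 0.138, 0.182) or null P49 replicate 3 (0.0647), range 0.00353 to 0.811. Crtam age in wild type did not pass without wild-type P21 replicates 1, 2 and 3 (0.0955, 0.117, 0.113) or wild-type P49 replicates 2 and 3 (0.176, 0.159), range 0.00428 to 0.176. Aplnr age in wild type lost its call without wild-type P21 replicates 1 and 2 (0.0638, 0.0671), range 0.00128 to 0.0671. Cdkn1c age in wild type did not pass without wild-type P21 replicates 1, 2 and 3 (0.0913, 0.112, 0.195), wild-type P49 replicates 1, 2 and 3 (0.0535, 0.183, 0.145) or null P49 replicate 3 (0.0636), range 0.00507 to 0.195. Col4a1 age in wild type lost its call without wild-type P21 replicates 1 and 3 (0.0573, 0.0568) or wild-type P49 replicates 2 and 3 (0.0738, 0.0667), range 0.00115 to 0.0738. Mog age in wild type did not pass without wild-type P49 replicate 2 (0.0657), range 0.000721 to 0.0657. Sqle age in wild type lost its call without wild-type P21 replicates 1 and 2 (0.0955, 0.0813) or wild-type P49 replicates 2 and 3 (0.122, 0.0998), range 0.00144 to 0.122. Fdps age in wild type did not pass without wild-type P21 replicates 1, 2 and 3 (0.0638, 0.0574, 0.108) or wild-type P49 replicates 2 and 3 (0.124, 0.112), range 0.00367 to 0.124.

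In null animals, genes of microglia, lysosome and complement rose between P21 and P49 and 20 Purkinje cell genes fell. Lyz1 rose by 3.69 ± 0.48, Lyz2 by 3.65 ± 0.36, Th by 3.42 ± 0.38 (adjusted p = 0.000149), Tyrobp by 2.70 ± 0.17 (2.44e-06) and Clec7a by 2.65 ± 0.22. Alas2, the erythroid enzyme of haem synthesis, fell by 3.27 ± 0.58 (0.00498), a size that is uncertain because its P49 null values of 8.74, 8.98 and 9.31 are not shown to be above background, Necab3 by 1.97 ± 0.16, Aplnr by 1.95 ± 0.26, Col4a1 by 1.94 ± 0.21 and the cell cycle inhibitor Cdkn1a by 1.79 ± 0.32. All 15 activated microglia genes rose (15 adjusted over the list alone; adjusted p = 0.00425 with an estimated correlation), as did 14 of 17 microglia core genes (14 adjusted over the list alone; adjusted p = 0.00425 with an estimated correlation) and 17 of 41 lysosomal genes (21 higher and 1 lower adjusted over the list alone; adjusted p = 0.00809 with an estimated correlation). Of 6 complement genes 4 rose (6 adjusted over the list alone; adjusted p = 0.0133 with an estimated correlation). Of 30 Purkinje cell genes 20 fell, among them Itpka (-1.36 ± 0.23), Ebf2 (-1.16 ± 0.19), Cacna1g (-1.11 ± 0.16) and Atp2a3 (-1.10 ± 0.19), with 23 when adjusted over the list alone, and the shift of the list was lost (adjusted p = 0.0595 with an estimated correlation). Of 12 reactive astrocyte genes 5 rose, with Gfap at 2.52 ± 0.17 and Vim at 1.23 ± 0.17, also 5 adjusted over the list alone (adjusted p = 0.0527 with an estimated correlation). Of 19 cholesterol synthesis genes 4 fell, with Hmgcs1 at -0.64 ± 0.12 and Sqle at -0.66 ± 0.16, and 8 when adjusted over the list alone (adjusted p = 0.0133 with an estimated correlation). Further probe sets of Cdkn1a and Atp2a3 gave -1.34 (adjusted p = 0.122) and -0.81 (0.0894). Hmgcs1 age in Npc1 null lost its call with only the arrays of the 2 groups (0.0751), in a range of 0.000161 to 0.0751 over all alternatives, and Ebf2 age in Npc1 null without the 3 doubtful arrays (0.0616), in a range of 0.00175 to 0.0616. Sqle age in Npc1 null lost its call without null P21 replicate 2 (0.0542) or null P49 replicates 2 and 3 (0.128, 0.127), range 0.0119 to 0.202 over all alternatives.

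In limma 218 genes were higher and 270 lower with age in null animals, beside 1635 at an unadjusted p under 0.05. The groups of 481 of these 488 do not overlap (22.5% of all genes, against 10% by chance), and 1 has a clone name. For age in Npc1 null genes higher and age in Npc1 null genes lower, there were 78 and 93 without null P49 replicate 2, and 90 and 127 without null P49 replicate 3. Without the 3 doubtful P21 arrays 274 of the 488 calls were shared.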

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

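Among the tests in this part, the actin ratio, both tests of swapped arrays, both tests of mixed male and female RNA, the test of Ttr and the choroid plexus covariate were chosen only after the result was seen.

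The genotype difference changed with age for 43 genes in the limma interaction test, which is what marks the following values. The difference at P49 exceeded that at P21 by log2 3.37 for Lyz2, 3.30 for Th, 2.83 for Gfap, 2.82 for Fcer1g, 2.80 for Tyrobp, 2.79 for Lgals3, 2.56 for Clec7a, 2.31 for C1qa, 2.12 for C1qc and 2.05 for Fcgr3. It was more negative at P49 by -1.87 for B3gnt5, -1.61 for Itpka, -1.41 for Col18a1, -1.36 for Ebf2, -1.33 for Cacna1g, -1.30 for Inpp4a, -1.26 for Ptprr, -1.25 for Krt81, -1.20 for Kcnma1 and -1.11 for Rgs8. Of these 20 genes Lyz2, Gfap, Tyrobp, C1qa, C1qc, Fcgr3, B3gnt5 and Inpp4a were called whichever of the 12 arrays was left out of the fit. Th and Clec7a were called in the 9 fits that tested them and were not among the genes tested without P49 null replicate 1, 2 or 3.

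B3gnt5 genotype by age interaction lost its call with the average of probe sets (adjusted p = 0.154, range 0.00101 to 0.154 over all alternatives), and a further probe set of Col18a1 gave -0.98 (0.119). The other 10 depended on single arrays, which were left out of limma's fit in turn. Fcer1g genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1 and 3 (0.0733, 0.0881), wild-type P49 replicates 1, 2 and 3 (0.0773, 0.0517, 0.0708) or null P49 replicates 2 and 3 (0.0894, 0.0902). Lgals3 genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1, 2 and 3 (0.0502, 0.051, 0.077), wild-type P49 replicates 1 and 2 (0.054, 0.0753) or null P49 replicates 2 and 3 (0.0818, 0.0902). Itpka genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1, 2 and 3 (0.0982, 0.0765, 0.175), null P21 replicates 1, 2 and 3 (0.057, 0.0502, 0.0961), wild-type P49 replicates 1, 2 and 3 (0.152, 0.136, 0.0852) or null P49 replicates 2 and 3 (0.114, 0.183). Col18a1 genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1 and 3 (0.0733, 0.0959), null P21 replicate 3 (0.0505), wild-type P49 replicates 1, 2 and 3 (0.0691, 0.0992, 0.0708) or null P49 replicate 3 (0.0902). Ebf2 genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1 and 3 (0.115, 0.156), null P21 replicates 2 and 3 (0.0552, 0.0961), wild-type P49 replicates 1, 2 and 3 (0.0909, 0.133, 0.142) or null P49 replicates 1, 2 and 3 (0.071, 0.15, 0.0902). Cacna1g genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1 and 3 (0.0503, 0.069), wild-type P49 replicates 1 and 2 (0.0626, 0.0517) or null P49 replicates 2 and 3 (0.0659, 0.0742). Ptprr genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1, 2 and 3 (0.0966, 0.0941, 0.111), wild-type P49 replicates 1, 2 and 3 (0.109, 0.101, 0.116) or null P49 replicates 2 and 3 (0.126, 0.156). Krt81 genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1, 2 and 3 (0.0893, 0.0693, 0.15), null P21 replicates 2 and 3 (0.0536, 0.067), wild-type P49 replicates 1, 2 and 3 (0.137, 0.128, 0.142) or null P49 replicates 1, 2 and 3 (0.0573, 0.15, 0.156). Kcnma1 genotype by age interaction lost its call, by adjusted p, without wild-type P49 replicates 1 and 3 (0.054, 0.0508) or null P49 replicate 2 (0.0652). Rgs8 genotype by age interaction lost its call, by adjusted p, without wild-type P21 replicates 1 and 3 (0.0578, 0.0804), null P21 replicate 3 (0.0612), wild-type P49 replicates 1, 2 and 3 (0.0823, 0.0976, 0.0708) or null P49 replicates 2 and 3 (0.0659, 0.0902). Over all alternatives the adjusted p ran from 0.000353 to 0.0902 for Fcer1g, 0.00171 to 0.0902 for Lgals3, 0.0023 to 0.183 for Itpka, 0.00349 to 0.0992 for Col18a1, 0.0197 to 0.168 for Ebf2, 0.00435 to 0.0742 for Cacna1g, 0.00349 to 0.156 for Ptprr, 0.0224 to 0.156 for Krt81, 0.00491 to 0.0652 for Kcnma1 and 0.004 to 0.0976 for Rgs8.

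Other splits of the arrays within both ages bear on how far chance can be excluded for the interaction. Of 100 splits drawn from 200, the real one included, 10 gave at least 43 genes and the highest gave 166, a share that by itself does not exclude chance. All 10 keep the P49 genotypes apart, as 13 of the 100 drawn do, so they carry the genotype difference at P49 and are not draws without any difference. With the P49 genotypes mixed the highest count was 1 gene, and splits that call several times the real count point to the P49 difference as a structure of the samples. At least 7 lists shifted in 60 of the 100 splits, 47 of them with the P49 genotypes mixed, with a highest of 17 in another split, so the number of shifted lists is no more than other splits give.

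For the comparisons of 3 arrays with 3 arrays there are only 10 splits, which is too few for a share under 0.05. At P21 the real split gave 5 genes and 13 lists (1 split as large for each) against 1 gene and 10 lists in the highest other split, and at P49 208 genes and 17 lists against 0 genes in limma, beside 887 at an unadjusted p under 0.05 in the real comparison, and 14 lists. With age in wild type it gave 55 genes and 8 lists against 0 genes and 8 lists, with 3 of the 10 splits giving as many lists, and with age in null animals 488 genes and 15 lists against 1 gene and 13 lists. Of the 208 genes called at P49, 77.4% had the same sign at P21, and 2 of 10 splits of the P21 arrays went as far, with 77.9% in another split.

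Sex-linked genes outside the comparisons went against the labels on 4 arrays, of which 3 are at P21 and labelled female, with Eif2s3y at 12.72 on wild-type replicate 2, 9.25 on null replicate 2 and 12.67 on null replicate 3. A swap of arrays between genotypes is argued against by Npc1, since 0 arrays had a level inside the range of the other genotype (an ordering of 6 against 6 arrays and not a test by limma, in which Npc1 did not pass). A swap of P49 null replicate 1, labelled male, with a P21 null array is argued against by its microglia core median of 1.66, when the P21 null arrays lie between 0.35 and 0.69. On null P21 replicate 3 the Xist level was 0.18 of the female level and the Y-linked level 1.09 of that on wild-type P21 replicate 2, a sum of 1.27 that leaves a mixture of male and female RNA possible. Its 5 Y-linked probe sets lay between 0.97 and 1.53 of the level on wild-type P21 replicate 2, so none shows a clear dilution by female RNA. That Xist share rests on 1 probe set, and of the other 2, deposited at 2467.2 and 138.0 on this array against 67.5 and 267.5 on wild-type P21 replicate 2, the dimmer shows no Xist above that array, so a mixture may account for this array but is not shown to. On null P21 replicate 2 the sum was 0.53, with 5 Y-linked probe sets between 0.07 and 2.36. Wrong sex records, a mixed sample and whatever sets this array apart over all genes cannot be told apart, while a biological explanation was not tested.

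Null P21 replicate 2 also stood apart over all genes, with correlations of 0.923 to 0.939 with the other arrays where the others had at least 0.951 among themselves, and principal component 1, with 26.3% of the variance, set at 41.5. Degraded RNA is argued against by the 3' over 5' ratio of actin, 1.38 on this array within a range of 1.32 to 1.63 over all arrays. A list of 21 transcripts picked as retained in the nucleus was written before their values were seen. It had 14 tested members, of which 13 were lower than on the other P21 null arrays, with a median of -1.0. On the other arrays the same median lay between -0.06 and 0.12, and 0% of 10000 random lists were as low. The random lists were matched on intensity alone, and the members include mRNAs of splicing factors such as Srsf5 and Srsf6, which may vary together. A loss of nuclear RNA in this preparation is therefore a candidate explanation that this list does not tell from a joint change of its genes. Xist RNA is itself held in the nucleus, so the low Xist of this array may belong to the same pattern, and a biological difference of this animal was not tested.

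Choroid plexus markers had a higher median in P49 null arrays, although no gene of 3 passed in limma. Ttr, the most abundant transcript of choroid plexus, varied by log2 5.18 within wild-type P21 and by 4.79 within null P21, more than the difference of 3.12 between the P49 genotypes. Within the P49 groups the range was smaller, 2.28 in wild type and 1.43 in null animals, and these groups do not overlap (12.76 to 15.03 against 16.23 to 17.66, which chance gives in 10% of genes), so unequal dissection of this tissue may account for the difference but is not shown to. With the choroid plexus median as a covariate, 84% (42 of 50) of the P49 calls in the microglia core, lysosome and Purkinje lists kept their call. The median ratio of the log2 differences was 1.01, and of all P49 calls 140 of 208 were shared. The slope of this covariate comes from spread within groups. Relative to wild-type P21 the median was -1.42, 1.62 and -0.6 on null P21 replicates 1, 2 and 3, and replicate 2 also stood apart over all genes. The covariate can therefore take up other differences of that array, and with it the calls with age in null animals went from 488 to 759. Choroid plexus content as a cause of P49 calls is thus not decided by this fit. A true change of choroid plexus in null animals stays open and was not tested.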

How the results depend on the processing

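The larger added offset, leaving out the 3 doubted P21 arrays and the choroid plexus covariate were tests chosen only after the result was seen. Of 60 shifts of gene lists, 24 kept their direction and call under every alternative run, 36 lost the call under at least 1 and 1 turned. Of 287 results for named genes 154 stayed the same, 86 lost a call, 43 gained one and 6 turned. The 154 include genes that were called in no fit, so they are not a count of stable calls. Among genes named by size or smallest p and called, those called in every fit without 1 array that tested them were 3 of 5 at P21 and 14 of 20 at P49. For the interaction they were 10 of 20, and with age 6 of 20 in wild type and 10 of 10 in null animals. Causes were not tested unless stated. An offset of 64 and a floor of 32 moved no count by over 1.5 times. Signal over background was not analysed here, so what dim genes lose is not known.

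For genotype at P21 genes higher (4), the count was 1 with only the arrays of the 2 groups and 2 with the 3 doubted P21 arrays left out. For genotype at P21 genes lower (1), it was 3 with values as deposited, every probe set, array weights, the larger added offset or the 3 doubted P21 arrays left out, 2 with trend and robust, 5 with the choroid plexus covariate, and 0 in limma, beside 790 genes of both signs at an unadjusted p under 0.05, with no filter, filter at the 60th percentile, average of probe sets, no trend, adjusted p under 0.01, sex as a covariate or only the arrays of the 2 groups. For genotype at P49 genes higher (119), it was 70 with the filter at the 60th percentile, 312 with array weights, 77 with adjusted p under 0.01, 233 with only the arrays of the 2 groups and 209 with the 3 doubted P21 arrays left out. For genotype at P49 genes lower (89), it was 257, 36, 167 and 147 with array weights, adjusted p under 0.01, only the arrays of the 2 groups and the 3 doubted P21 arrays left out. For genotype by age interaction genes higher (27), it was 51 with array weights, 13 with adjusted p under 0.01 and 41 with the choroid plexus covariate. For genotype by age interaction genes lower (16), it was 10 with no filter, 8 with no trend, 38 with array weights, 2 with adjusted p under 0.01, 29 with sex as a covariate and 27 with the choroid plexus covariate. For age in wild type genes higher (13), it was 7 with no trend, 92 with array weights, 1 with adjusted p under 0.01, 50 with only the arrays of the 2 groups and 65 with the 3 doubted P21 arrays left out. For age in wild type genes lower (42), it was 123, 11 and 76 with array weights, adjusted p under 0.01 and only the arrays of the 2 groups. For age in Npc1 null genes higher (218), it was 84 with adjusted p under 0.01, 140 with at least 1.5-fold, 68 with only the arrays of the 2 groups and 397 with the choroid plexus covariate. For age in Npc1 null genes lower (270), it was 90, 172 and 58 with adjusted p under 0.01, at least 1.5-fold and only the arrays of the 2 groups. Fewer calls with adjusted p under 0.01 or at least 1.5-fold follow from the stricter threshold.

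With an estimated correlation, genotype at P21 lists shifted fell from 13 to 3, genotype at P49 lists shifted from 17 to 8, age in wild type lists shifted from 8 to 1 and age in Npc1 null lists shifted from 15 to 7. Genotype by age interaction lists shifted went from 7 to 12 with values as deposited and to 12 with the 3 doubted P21 arrays left out.

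With each array left out in turn, genotype at P21 genes higher ran from 3 to 14 and genotype at P21 genes lower from 0 to 13, where the 0 is limma's count beside 790 genes at an unadjusted p under 0.05 with all arrays. Genotype at P49 genes higher ran from 65 to 190, genotype at P49 genes lower from 35 to 131, genotype by age interaction genes higher from 14 to 42, genotype by age interaction genes lower from 3 to 29, and genotype by age interaction lists shifted from 7 to 14. Age in wild type genes higher ran from 1 to 43, age in wild type genes lower from 12 to 69, age in wild type lists shifted from 5 to 11, age in Npc1 null genes higher from 78 to 292 and age in Npc1 null genes lower from 93 to 355. A group left with fewer arrays is assumed to vary like the other groups.

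The sign turned for the oxidative_phosphorylation genotype at P21 list, with a mean of 0.02 on values as deposited, for Rps9 genotype at P49 (-0.06) and Txn1 age in Npc1 null (0.49) with the average of probe sets, for Npc1 genotype by age interaction without Npc1_null_P21 replicate 2 (-0.03, in a range up to 0.90 without Npc1_null_P21 replicate 1) and with the 3 doubted P21 arrays left out (-0.28), for Gfap genotype at P21 (-0.05) with those arrays left out, which rests on 1 null array at P21, and for Folr1 genotype at P49 (-0.20) and Otx2 genotype at P49 (-0.37) with the choroid plexus covariate, which is built from these genes.

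The replicate numbers were not shown to pair the animals. Of 18 pairs of arrays with the same number, 6 had deviations correlated over 0.1, with a range of -0.175 to 0.189. For replicates 1, 2 and 3 the correlations were 0.189, 0.106 and 0.076 between the P49 genotypes, but -0.13, 0.121 and -0.175 between the P21 genotypes. Pairs with different numbers were not compared, so a batch shared by number is not excluded. With the number as a replicate block, genotype by age interaction genes lower went from 16 to 10, and 5 of 5, 183 of 208, 32 of 43, 45 of 55 and 395 of 488 calls were kept at P21, at P49, for the interaction, and with age in wild type and null animals. Sex as a covariate, with 1 animal labelled male, amounts to leaving out P49 null replicate 1. It uses labels that the sex-linked genes go against on 4 arrays, so it is not a check of sex, and sex by these genes was not fitted.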

Other observations

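Among the tests in this part, that of microglial activation was chosen only after the result was seen.

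No further list at P49 held its call with an estimated correlation. In the list of brainstem neurons at P49, Th rose by 2.88 ± 0.38 while the neurofilament gene Nefh fell by 0.84 ± 0.17 (limma adjusted p = 0.0147), 1 gene each way of 5 tested and also 1 each way adjusted over the list alone, with a median of -0.15 and a mean of 0.42 (adjusted p = 0.936). Nefh genotype at P49 lost its call without wild-type P49 replicates 1, 2 and 3 (0.0647, 0.0573, 0.0624) or null P49 replicates 1 and 2 (0.0687, 0.0595), with a range over all alternatives of 0.000226 to 0.0687. Th was at 12.15, 12.47 and 12.53 on the P49 null arrays and between 8.47 and 9.91 on the other 9. Purkinje cells express Th as well, so the list's name does not fix where this transcript comes from. In the immediate early list the transcription factor gene Jun rose by 0.88 ± 0.11 (adjusted p = 0.000435; 0.51 and 0.189 for a further probe set), 1 of 9 genes and 2 adjusted over the list alone, and the list's call was lost (adjusted p = 0.232 with an estimated correlation). The shift immediate_early genotype at P49 list was also lost without wild-type P49 replicate 2 (0.196), in a range of 5.4e-05 to 0.232 over all alternatives. Ribosomal protein genes had medians of 0.11 at P21 and 0.09 at P49, with 0 of 30 called in limma at either age and 0 adjusted over the list alone (adjusted p = 0.194 and 0.129 with an estimated correlation).

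Oxidative phosphorylation genes had medians of -0.07 at P21 and -0.10 at P49, with 0 of 43 called in limma (adjusted p = 0.623 and 0.381 with an estimated correlation). Oxidative stress genes had a median of 0.07 at P49 with 0 of 17 called in limma and 1 adjusted over the list alone (adjusted p = 0.0574 with an estimated correlation). At P21 the reactive astrocyte list (median 0.16; adjusted p = 0.374 with an estimated correlation) and the cholesterol efflux list (0.29; adjusted p = 0.317 with an estimated correlation) lost their calls. At P49 no shift was called for endothelium and pericytes (adjusted p = 0.645), oligodendrocyte precursors (0.317), the unfolded protein response (0.565), autophagy (0.944), the cell cycle (0.511), immature neurons (0.532) or synaptic vesicles (0.142). With age in null animals, 2 of 7 antigen presentation genes rose (3 adjusted over the list alone; adjusted p = 0.0133 with an estimated correlation), and of 20 genes of astrocytes and Bergmann glia 2 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.0434 with an estimated correlation). The calls in null animals were lost for myelin (median -0.21; adjusted p = 0.495 with an estimated correlation), interferon response (0.54; adjusted p = 0.0927 with an estimated correlation), oxidative stress (0.24; adjusted p = 0.0698 with an estimated correlation), immature neurons (-0.26; adjusted p = 0.299 with an estimated correlation), oxidative phosphorylation (-0.09; adjusted p = 0.499 with an estimated correlation) and ribosomal proteins (0.14; adjusted p = 0.131 with an estimated correlation).

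The lysosome and microglia lists share 4 tested members, so the lysosomal shift at P49 might only repeat the microglial one. Without these 4, 13 of 37 lysosomal genes rose in limma and none fell, with a median of 0.38 (adjusted p = 1.23e-23 at the preset correlation and 0.00118 with an estimated correlation), which argues against the shared members as the whole source. Whether lysosomal genes rose in microglia or in other cells was not tested.

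A hypothesis was that microglial markers at P49 change beyond a larger number of cells, which would set genes of resting microglia below those of activated microglia. The difference of the 2 medians between null and wild type was -0.39, with null arrays at -0.48, -0.40 and -0.23 and wild-type arrays between 0.00 and 0.03. The arrays do not overlap and differ in the direction the hypothesis needs, but the difference is short of the bound of 1. That bound was chosen after the result was seen, so this test does not decide between number and state. Of the resting genes, named outside the naming rule after their values were seen, Cx3cr1 (1.71), Olfml3 (1.61) and Csf1r (1.35) were called in limma, and P2ry12 (0.56) and Tmem119 (-0.22) were not.

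A further hypothesis was that Purkinje cells without zebrin are lost before those with it, which would lower their markers more. The mean of the zebrin-negative markers minus that of the zebrin-positive markers differed by -0.42 between null and wild type at P49, with null arrays at -0.49, -0.37 and -0.40 and wild-type arrays at -0.13, 0.22 and -0.09, the direction the hypothesis needs. The P21 null arrays were at -0.22, -0.70 and 0.15, a spread wider than the P49 difference, at an age when the Purkinje list had a median of 0.00. The result rests on 5 genes that do not move alike, since Ebf2 was -1.16 and Plcb4 -0.25 among the negative markers, and Slc1a6 -0.83, Plcb3 -0.05 and Aldoc 0.03 among the positive ones. Astrocytes also express Aldoc, and 3 arrays against 3 cannot give an exact p below 0.1, so this stays a hypothesis.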
